A study of Mus musculus with 7 samples.

How the data were processed

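RNA was extracted from fresh cortex with TRIzol and made into strand-specific poly(A) libraries, per the labels' protocols. HISAT2, HTSeq and the mm10 genome build are named in the submitters' processing notes, and their versions, the gene annotation and the gene lengths used are not given in the sources used here. The deposited table holds TPM values per gene and sample, per the file headers, and every column sums to 1000000 TPM. TPM divides the reads of a gene by its length and scales each library to the same total, so a few abundant transcripts that differ between libraries shift all other values. The table lists genes by symbol, with 147 symbols on more than 1 row (297 rows), which were kept as separate rows. No column of another sample was present, and no pair of columns was identical.

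TPM keeps no read total. The values were therefore multiplied by the exon-union length of each gene in GENCODE vM21 (the mm10 build), which had a unique symbol for 48920 rows (85.9% of the table). In each library the most frequent low value was taken as 1 counted unit, and the low values fell on whole and half-integer multiples of it. Of the values up to 10 units, 64.1 to 72.2% lay within 0.05 of a whole number and 95.1 to 96.1% within 0.05 of a whole or half-integer number. The total divided by that unit gave 57.2 M units (M, 1000000) in WT replicate 3, 66.4 to 72.5 M in the other WT libraries and 71.2 to 79.4 M in P213L. These are estimates that rest on the vM21 lengths and on that choice of unit. No count test was run, since the counts themselves are not in the table.

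Samples were grouped by their titles. The values were tested as log2(TPM + 0.5) for genes with a mean of at least 1 TPM over the 7 samples, with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are P213L over WT on that scale, which understates the change of low genes. Single values were compared by exact permutation over all 35 splits of the 7 samples into 4 and 3, two-sided, where the smallest possible p is 0.0286. Gene lists for stages of the oligodendrocyte lineage, other cell types, neighbouring regions, stress and basic cell functions were fixed before the data were examined, 39 with at least 3 tested members. They were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Camera asks whether a list differs from the other genes. Fry asks whether a list moves to 1 side by itself.

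The genes named were also set beforehand: Hnrnph2 and its paralogs, the genes with the largest changes past the threshold or, with fewer than 3 in a direction, the 6 with the smallest p in that direction, up to 4 members of each list with the smallest p, and a fixed set of lineage genes. Gene models and clones were left out of the largest changes, and 2 genes that the rule selects are not reported here. Ttr as a sample marker, Xist and Ddx3y belong to the lists. The microRNA rows as a class and the rows Rn18s-rs5, Rn7sk, Malat1, Bc1, Meg3, Mirg and Rian were chosen after their values were seen.

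The alternatives set beforehand were other pseudocounts, filters and scalings, fits without the trend, robust or with sample weights, the replicate number as a block, each sample left out in turn, and other set tests. Sex as a covariate was not run because all 7 samples were male by expression. A protein-coding filter, removal of a trend on gene length and GC content, leaving out WT replicates 2 and 3 together and leaving out WT replicate 3 with an estimated correlation were chosen after seeing the data. The fit and the list test were tested on simulated data drawn for the 17582 genes with the means and spread of the real libraries. Each of 20 sets held 200 changed genes of mixed sizes, and the myelinating list was shifted by -0.25 as well. Recovered were 11.8% of genes changed by 0.58 on the log2 scale, 51% of those changed by 1, 85.3% by 2 and 94.6% by 3. On average 6.10 unchanged genes were called per set. The share recovered after adjustment depends on how many genes change. Simulated genes varied independently, which real genes do not. Figures were drawn with matplotlib 3.10.9, and lengths were joined with pandas 2.3.3 in Python 3.11.15.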

Results

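Gene expression was measured by RNA sequencing of cerebral cortex from mice at postnatal day 7. The series compared 4 wild-type (WT) samples with 3 samples from mice carrying the P213L variant of Hnrnph2, an X-linked gene that encodes a heterogeneous nuclear ribonucleoprotein, a class of RNA-binding proteins that act in splicing. The title of the series names oligodendrocyte differentiation and myelination as its subject. Oligodendrocytes are the glial cells that wrap axons in myelin, and in the mouse cortex they are only beginning to do so at this age. The deposited table gave transcripts per 1000000 (TPM) for 56941 rows, and 17582 genes with a mean of at least 1 TPM were tested. Library depth, estimated from the most frequent low value in each library, ran from 57.2 to 79.4 M counted units (M, 1000000). The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples.

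WT replicate 3 stood apart from the rest. Its correlation with the other 6 libraries across the tested genes was 0.943 to 0.949, against 0.981 to 0.992 among those 6, and 28367 genes had a value above 0 there, against 31387 to 32526. Its scores of several neuronal and synaptic gene lists were low and those of the ribosomal and respiratory chain lists high. The choroid plexus product Ttr, a thyroid hormone carrier, stood at 1216 TPM in WT replicate 2 and at no more than 1.36 TPM in the other 6 libraries. Some rows of ribosomal or nuclear RNA, chosen after their values were seen, also differed between the groups. The ribosomal RNA row Rn18s-rs5 held 1.31 to 2.41% of TPM in WT and 2.56 to 4.12% in P213L, and the nuclear RNA Malat1 stood at 89.9 to 385.2 TPM in WT and 488.2 to 568.7 TPM in P213L. All 7 samples had the pattern of males, with the Y-linked Ddx3y at 23.4 to 44.1 TPM and Xist at no more than 0.0419 TPM.

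**Figure D1:**
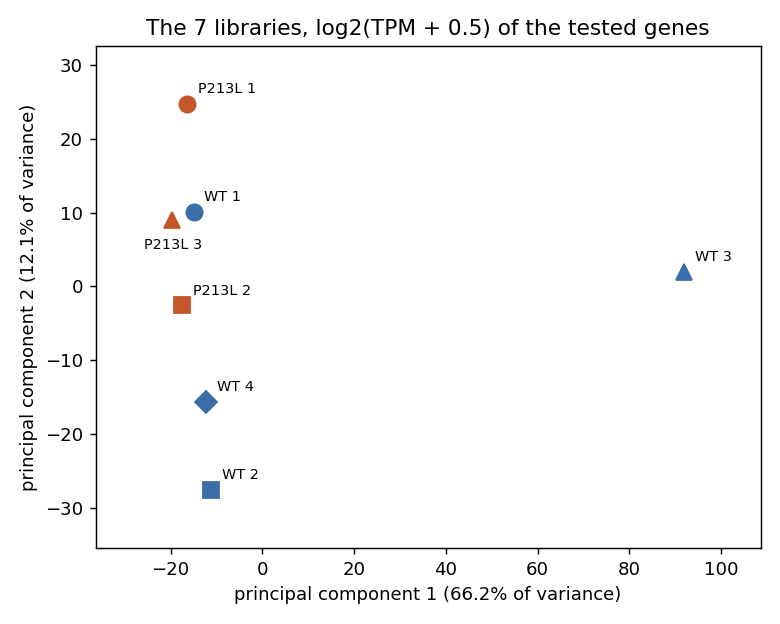
Principal components 1 (66.2% of the variance) and 2 (12.1%) of log2(TPM + 0.5) of the tested genes, 1 point per library, WT in blue and P213L in orange. WT replicate 3 lies at 91.9 on component 1, and the other 6 libraries lie between -19.6 and -11.2.

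Hnrnph2 itself (mm10, chromosome X, 134601179 to 134607060, plus strand) stood at 87.0 ± 5.66 TPM in WT (SD, n = 4) and 82.0 ± 5.39 TPM in P213L (SD, n = 3). The log2 fold change was -0.08 ± 0.10 (SE; limma adjusted p = 0.831; exact permutation p = 0.257), so the difference was within the spread between samples. The variant changes the protein, so this level does not check the labels. The paralogs showed no difference past the threshold either. Hnrnph1 had a log2 fold change of 0.05 ± 0.10, Hnrnpf of 0.08 ± 0.13 and Hnrnph3 of 0.14 ± 0.13 (SE). With median-of-ratios scaling, Hnrnph1 came to -0.04. These paralogs share similar sequence, so reads that fit more than 1 of them leave the values uncertain.

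Some genes of myelin had lower values in P213L cortex, none of them past adjustment over all genes in limma. Mobp, a component of compact myelin, stood at 9.42 ± 0.496 TPM in WT and 4.21 ± 0.974 TPM in P213L (SD, n = 4 and 3). Mbp, which holds the membrane layers of myelin together, stood at 102.7 ± 8.57 and 73.4 ± 4.84 TPM, and Mag, an adhesion protein of the membrane next to the axon, at 14.6 ± 2.12 and 9.24 ± 0.850 TPM. All 3 P213L values lay below all 4 WT values for each of these genes. Mog, a protein of the outer face of the sheath, did not follow them, at 11.8 ± 1.73 TPM in WT and 12.5 ± 0.786 TPM in P213L.

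As a group, the 32 tested genes of the myelinating oligodendrocyte list fell relative to all other genes, with a mean log2 fold change of -0.15 and a median of -0.08 (camera on the limma fit, adjusted p = 2.08e-06; adjusted p = 0.270 with an estimated correlation). The per-sample mean of the list was lower in all 3 P213L samples than in all 4 WT samples (exact permutation p = 0.0286, the smallest that 35 splits can give). This p does not pass adjustment over the lists, and it could do so only if most lists reached the same floor. Of the 32 members, 21 were lower and 11 higher. Adjusted over the list alone, 4 members fell, among them Mobp (log2 fold change -1.09 ± 0.16, SE), Mag (-0.63 ± 0.15) and Mbp (-0.48 ± 0.11). None passed adjustment over all genes tested. Cnp, an enzyme of uncompacted myelin, had a log2 fold change of -0.22 ± 0.09 and Mog of 0.08 ± 0.14 (SE; adjusted p = 0.827 and 0.861 over all genes in limma). The mean of the myelinating list was -0.23 with median-of-ratios scaling and -0.24 with quantile normalization, and -0.16 without WT replicate 3.

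**Figure D2:**
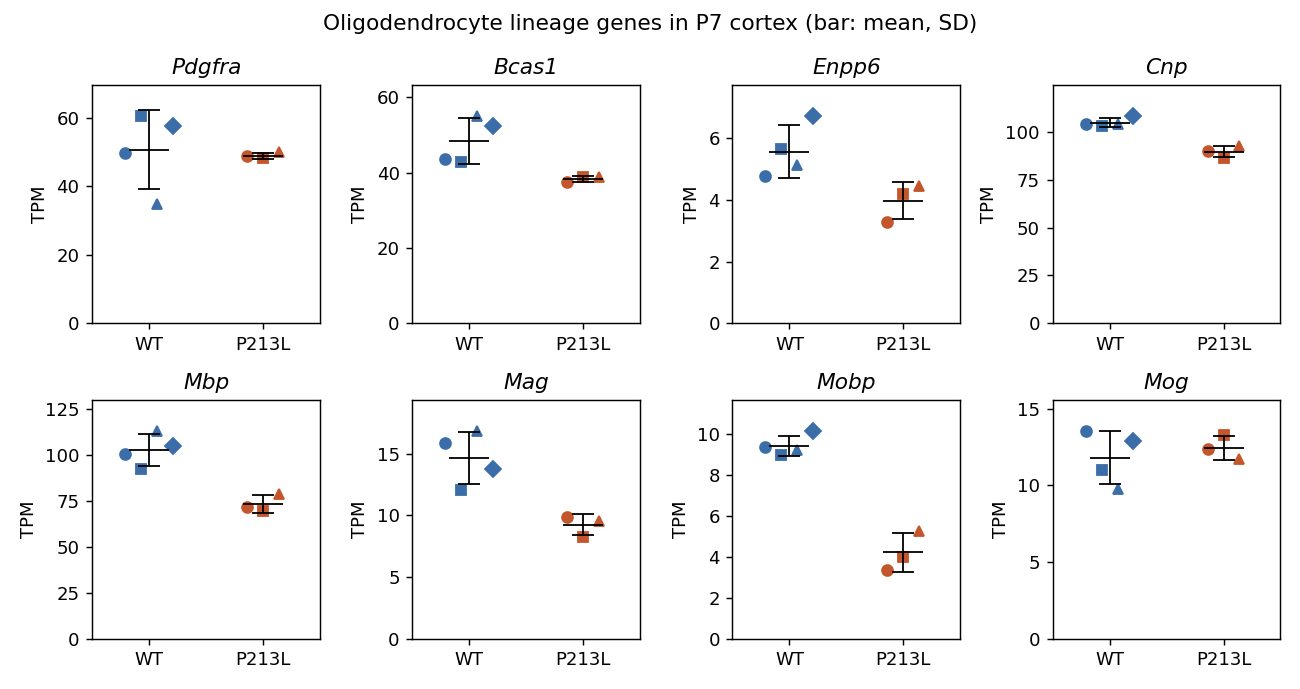
TPM (linear axis from 0) of 8 genes of the oligodendrocyte lineage in each library, WT (n = 4) in blue and P213L (n = 3) in orange. Bars give the mean and SD. Mobp, Mbp, Mag, Cnp, Enpp6 and Bcas1 show no overlap between the groups, and Pdgfra and Mog overlap.

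Markers of committed and newly formed oligodendrocytes, the stage before myelination, gave a mixed picture. Bcas1, which marks cells starting to myelinate, stood at 48.4 ± 6.21 TPM in WT and 38.4 ± 0.833 TPM in P213L, and Enpp6, a marker of newly formed cells, at 5.55 ± 0.850 and 3.97 ± 0.605 TPM (SD, n = 4 and 3). The long noncoding gene 9630013A20Rik had a log2 fold change of -0.83 ± 0.29, Neu4 of -0.22 ± 0.12 and Gpr17, a receptor of committed cells, of 0.14 ± 0.27 (SE). Adjusted over the list alone, 0 of 19 members passed in limma, with 3 lower at an unadjusted p under 0.05. The list as a whole did not pass (mean log2 fold change -0.06, median -0.01, camera adjusted p = 0.0836). Without WT replicate 3 its mean was -0.16 with an adjusted p of 7.55e-04 in camera (adjusted p = 0.418 with an estimated correlation). The list also passed with sample weights, where that library carried little weight, and with median-of-ratios scaling or quantile normalization. It did not pass with mitochondrial genes removed, or with median-of-ratios scaling and the replicate number as a block.

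Oligodendrocyte precursors and the regulators of the lineage showed no difference past the threshold. Pdgfra, the growth factor receptor that marks precursors, stood at 50.7 ± 11.5 TPM in WT and 49.0 ± 0.935 TPM in P213L, and Cspg4, a proteoglycan of the same cells, at 12.6 ± 3.39 and 13.5 ± 0.769 TPM (SD, n = 4 and 3). The precursor list of 17 genes had a mean log2 fold change of 0.09 and a median of 0.08, while camera placed it slightly below the other genes (adjusted p = 0.924). Without WT replicate 3 its mean was -0.06. Of the transcription factors of the lineage, Olig2 had a log2 fold change of 0.33 ± 0.22, Sox10 of 0.14 ± 0.18 and Myrf, which switches on myelin genes, of -0.20 ± 0.27 (SE). Their list had a mean of 0.12 (camera adjusted p = 0.461). Without WT replicate 3 the list mean was 0.007, and Olig2 had 0.12, Sox10 -0.002 and Myrf -0.44.

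The stages were also set against each other within each sample. The mean of the myelinating list less that of the precursor list was -1.29 ± 0.30 in WT (SD, n = 4) and -1.53 ± 0.02 in P213L (SD, n = 3), a difference of -0.24 that did not pass (exact permutation p = 0.229, two-sided). WT replicate 3 held -0.87 and the other WT samples -1.55 to -1.34, and without it the difference was -0.10. The committed list less the precursor list differed by -0.15 (exact permutation p = 0.0571). These were 2 of 5 such differences computed, and none was past 0.05 before adjustment.

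Among the other cell types, microglial genes fell as a group. The list of 18 had a mean log2 fold change of -0.17, with 17 members lower (camera adjusted p = 1.06e-04; adjusted p = 0.411 with an estimated correlation). Siglech, a lectin of resting microglia, had a log2 fold change of -0.43 ± 0.14, Gpr34 of -0.52 ± 0.20 and P2ry12, their purine receptor, of -0.55 ± 0.23 (SE), and 0 members passed adjusted over the list alone in limma, with 3 lower at an unadjusted p under 0.05. The astrocyte list did not pass (mean -0.05, camera adjusted p = 0.0959), and S100b in it stood at 46.6 ± 12.2 TPM in WT and 31.4 ± 2.19 TPM in P213L (SD, n = 4 and 3). The myelinating list less the astrocyte list differed by -0.10 (exact permutation p = 0.429), and the myelinating list less the microglial list by 0.02 (exact permutation p = 0.83), so the fall of the myelin genes was not separated from these glial lists.

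Immediate early genes, which neurons switch on with activity and cells with stress or handling, rose as a group (mean log2 fold change 0.24, 19 of 23 members higher, camera adjusted p = 0.00476; adjusted p = 0.576 with an estimated correlation). Fos stood at 8.16 ± 1.44 TPM in WT and 15.8 ± 6.39 TPM in P213L, and Btg2 at 11.0 ± 0.628 and 17.4 ± 3.95 TPM (SD, n = 4 and 3). Genes of meningeal fibroblasts, which lie on the cortical surface and come with the dissection, also rose (mean 0.29, 12 of 15 higher, camera adjusted p = 0.0151; adjusted p = 0.762 with an estimated correlation), with Col1a1, a collagen chain, at 41.0 ± 16.7 and 70.0 ± 23.2 TPM. The groups overlapped for Col1a1 and not for Foxc1 of the same list, at 8.86 ± 0.904 TPM in WT and 11.4 ± 0.455 TPM in P213L. With a trend on gene length and GC content removed, the immediate early list did not pass (mean 0.11, adjusted p = 0.108). The mean of the meningeal list was 0.16 without WT replicate 3, and its call was lost without WT replicate 4 (adjusted p = 0.0917) or P213L replicate 2 (adjusted p = 0.0965).

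Lists of the respiratory chain and of ribosomal proteins were lower, and the glycolysis and hypoxia list was not (mean log2 fold change 0.02, 15 of 25 higher, camera adjusted p = 0.483). Mitochondrially encoded transcripts fell by 0.61 on the log2 scale on average, with 20 of 21 lower (camera adjusted p = 3.13e-09; adjusted p = 0.576 with an estimated correlation). P213L replicate 1 was lowest, with 4.17% of all TPM in these genes, while P213L replicates 2 and 3 held 6.89 and 5.68%, within the range of the 4 WT samples (5.58 to 8.51%). The mean log2 value of the list was lower in all 3 P213L samples (6.56, 7.72 and 7.78) than in the 4 WT samples (7.85 to 8.26). The exact permutation p was 0.0286, the smallest possible. It does not pass adjustment over the lists, which would need most lists to reach that floor. Without P213L replicate 1 the mean fold change was -0.21, and the list passed in camera at the preset correlation with any 1 library left out (highest adjusted p = 1.91e-04). Nuclear genes of the respiratory chain fell (mean -0.22, 30 of 32 lower, adjusted p = 3.13e-09; adjusted p = 0.762 with an estimated correlation), as did cytosolic ribosomal protein genes (mean -0.15, 75 of 84 lower, adjusted p = 6.46e-09; adjusted p = 0.772 with an estimated correlation). WT replicate 3 had the highest score of both, and without it the means were -0.08 and 0.02 (adjusted p = 7.56e-04 and 0.390 in camera; adjusted p = 0.477 and 0.889 with an estimated correlation). The choroid plexus list fell (mean -0.54, adjusted p = 0.0390; adjusted p = 0.772 with an estimated correlation), and without WT replicate 2 its mean was 0.10 (adjusted p = 0.819).

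**Figure D3:**
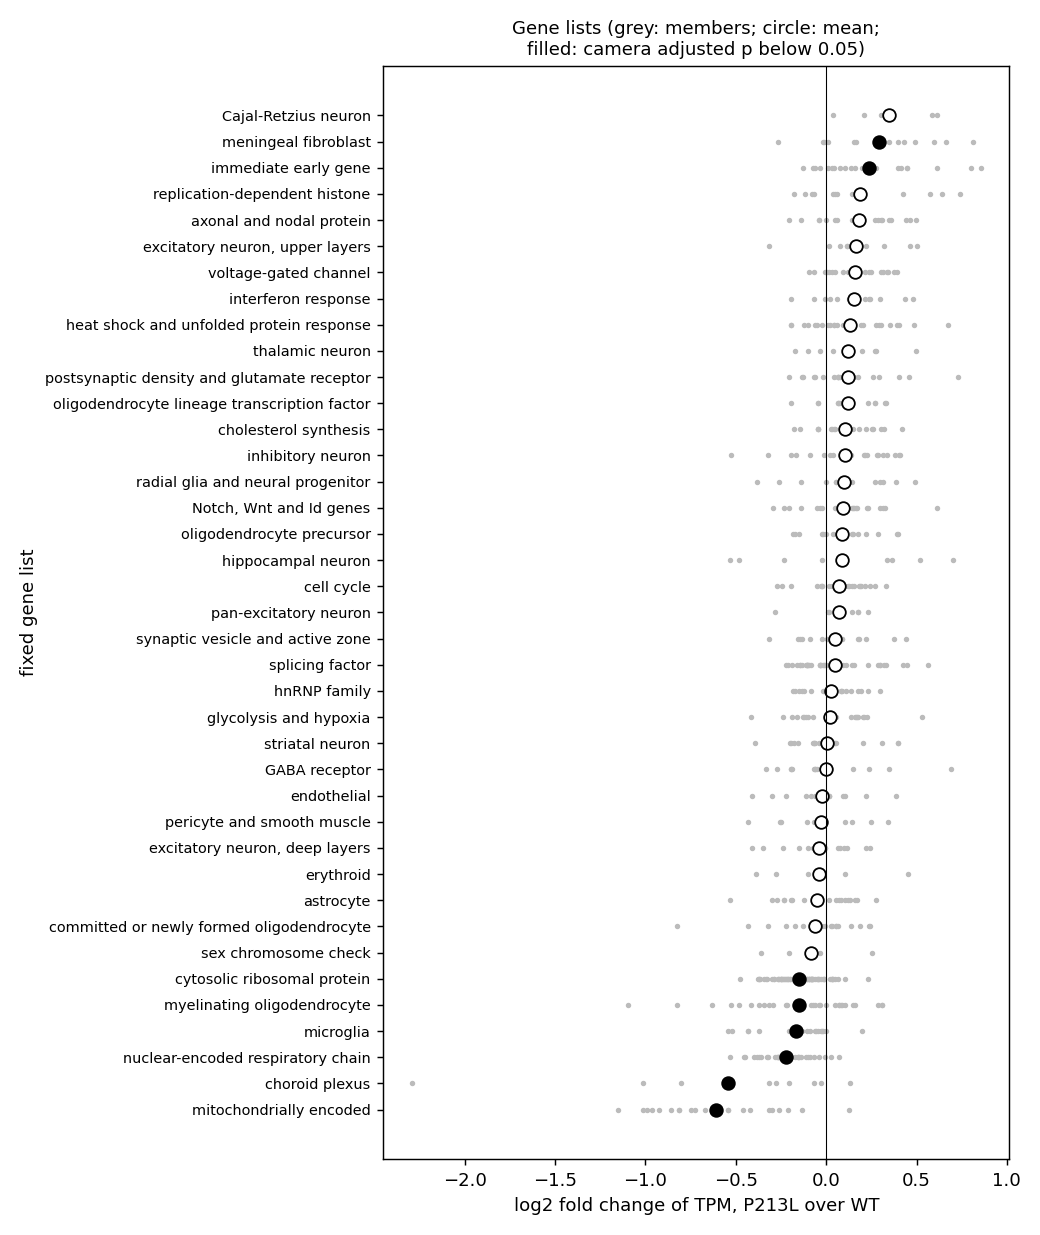
Log2 fold change of TPM, P213L over WT, for the tested members (grey points) and the mean (circles) of each of the 39 gene lists. Filled circles mark the 8 lists with a camera adjusted p under 0.05, 6 lower and 2 higher in P213L, and 0 of the 39 had one with an estimated correlation.

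Gene by gene, 0 of the 17582 genes passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.117. At an unadjusted p under 0.05 there were 657 genes, 415 higher and 242 lower in P213L, where chance alone gives 879.1. The share higher was 63.2%, and 52.0% with median-of-ratios scaling, 49.4% with quantile normalization and 53.2% with mitochondrial genes removed. The groups did not overlap for 8.69% of genes, against 5.71% by chance. The adjusted p of 0.117 in limma belonged to a gene model or clone, a class left out of the naming. The smallest adjusted p of a named gene was 0.597 (Mobp, limma). On the higher side, the named genes with the smallest p included the microRNA genes Mir493 (log2 fold change 1.49 ± 0.23, SE), Mir381 (1.83 ± 0.38) and Mir344-2 (2.04 ± 0.46). The small nuclear RNA gene Scarna17 (1.01 ± 0.17), Tm6sf2 (0.95 ± 0.21) and Igfbpl1 (0.52 ± 0.12) were also among them, and none passed. Mir493 (83 bases) stood at 4.38 ± 1.17 TPM in WT and 13.0 ± 2.70 TPM in P213L (SD, n = 4 and 3). Mir381 (75 bases) stood at 2.54 ± 1.51 and 9.52 ± 2.16 TPM. At such lengths and levels these rows rest on few counted units. The lower side included Mobp, Mbp, Prss22 (-1.20 ± 0.19), Mirlet7g (-1.26 ± 0.25) and the lens filament gene Bfsp2 (-0.60 ± 0.13). In simulated data with the spread of these libraries and 200 changed genes per set, 51% of genes changed by 1 on the log2 scale were recovered. Of those changed by 2, 85.3% were recovered, among 17582 genes. These shares hold for that many changed genes, and adjustment recovers a smaller share when fewer genes change. The count at an unadjusted p under 0.05 was 1574 without WT replicate 1, 1528 without WT replicate 3, and 266, 390 and 314 without P213L replicates 1, 2 and 3.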

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

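The tests of depth, of the length and GC trend, of tissue and blood, of short rows and of nuclear and non-polyadenylated RNA were chosen after the result was seen. Leaving out WT replicate 3 was set beforehand as an alternative, but its limits as a test of a pattern were chosen after the result was seen, and for the microRNA rows they were redefined after a first result, as were those of nuclear and non-polyadenylated RNA (from 2 SE to a 95% interval), of tissue and of blood. The tests over the splits of the samples were written before the values of the other splits were seen, except those of the gene counts in limma without sample weights, though the microRNA rows and the count with sample weights had been seen as patterns by then. Samples far from the other 3 of the WT group were looked for in 104 measures, and chance flags about 1 in 20 such groups of 4. There were 23, of which 16 were in WT replicate 3 and 4 in WT replicate 2.

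In WT replicate 3 several neuronal and synaptic lists lay far below the other 3 WT libraries. Mean log2 values were 4.31 for upper-layer excitatory neurons, 7.10 for all excitatory neurons, 3.59 for Cajal-Retzius neurons, 7.77 for synaptic vesicle genes, 5.78 for postsynaptic genes, 4.56 for voltage-gated channels and 6.40 for axonal proteins. Other neuronal lists were less far below, such as deep-layer excitatory neurons at 5.40 (5.50 to 5.59 in the other WT libraries) and inhibitory neurons at 4.96 (5.11 to 5.18). Transcription factors of the oligodendrocyte lineage stood at 3.52, with Olig2 at 5.32, Cspg4 at 3.01 and Gpr17 at 5.46. Nuclear respiratory chain genes (8.34) and ribosomal protein genes (8.75) lay far above. The library had 28367 genes above 0 and 16406 at 1 TPM or more, and a mean transcript length of 3251 bases weighted by TPM, against 3975 to 4019 in the other WT libraries.

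Lower depth is argued against, since the estimated depth of this library was 0.862 of the lowest of the other 6. Whether tissue from a neighbouring region contributed could not be decided. Median-of-ratios scaling gave this library the lowest factor of the 7, so its typical gene lay low in TPM. A list can then be low with or without such tissue. The choroid plexus, striatal, hippocampal, thalamic and meningeal lists all lay below the lowest of the other 6 libraries. The nearest lay at -1.09 of the range of those 6 from their maximum. More blood goes with the erythroid list, which exceeded their maximum by 0.662 of their range, though blood as the whole cause is argued against. Erythroid genes held 0.0904% of TPM, a rise of 0.0415 percentage points over the mean of the other 6, where the fall of the list of all excitatory neurons would need 21.6% of the RNA to be replaced. A trend on gene length and GC carried 22.1% of the variance of its deviations, the highest of the 7 by a small margin (9.26 to 21.5% in the other 6), and genes of 7053 bases or more had a median deviation of -0.60. As the whole cause the trend is argued against, since with it removed the median correlation with the other libraries was 0.960, against 0.989 to 0.991 for the rest. A loss of long transcripts during extraction or library making may account for part of the pattern, and no biological explanation was tested.

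The fall of the myelinating list rests neither on WT replicate 3, since its mean log2 fold change was -0.16 without it, nor on length or GC, since it was -0.24 with that trend removed. The 3 rows Rn18s-rs5, Rn7sk and Malat1, of nuclear or non-polyadenylated RNA, were higher in P213L without overlap. Bc1, another such row, was lower in P213L without overlap (means of 289.4 TPM in WT and 124.8 TPM in P213L), so the rise was not shared by all such rows. Whether the rise of those 3 rows is the whole cause of the fall could not be decided. The slope on them among libraries of the same group predicted a group difference of 0.0612 (95% interval -0.0898 to 0.212), against -0.15 observed. Without WT replicate 3 it predicted 0.0920 (-0.135 to 0.319), against -0.16. These intervals hold the error of the slope and not that of the observed difference. The margin is small without that library, so all or part of the fall stays open to it. Chance could not be excluded, because 3 of 35 splits, the genotype split among them, gave a camera p as small (-log10 p of 6.67 in the real split and 7.80 in the highest other). The others set WT replicates 1, 3 and 4, or WT replicate 2 with P213L replicates 1 and 2, against the rest. They differ from the genotype split in WT replicate 2, alone or with P213L replicate 3. The exact permutation test on the list mean gave p = 0.0286, which does not pass adjustment over the lists. Fewer myelinating cells and a change in their maturation with the genotype both stay open. The myelinating list less the precursor list did not differ past the threshold (-0.24, exact permutation p = 0.229, and -0.10 without WT replicate 3), and Mog did not follow the other myelin genes (0.08 ± 0.14, SE). Other splits also gave 8 or more lists past the threshold, as 17 of 35 did with the genotype split counted (highest other 17).

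The class of 191 tested microRNA gene rows had a median log2 fold change of 0.67 in P213L, with 146 higher, and 2 of 35 splits gave a median as far from 0 (highest other 0.78), so chance could not be excluded. Leaving out WT replicate 3 took the median to 0.25, which argues against that library as the whole cause as the rows still moved to the higher side together, though it carries most of the size. The rotation test fry in limma gave a p of 0.0413 without that library and 0.214 with it. Other rows under 150 bases had a median of 0.27 (95% of 10000 random draws of short rows from 0.15 to 0.36), and 0.02 without WT replicate 3. Both lay below the median of the microRNA rows. The draws took rows as independent, with WT replicate 3 included, and hold no spread between libraries. They therefore cannot decide whether short length is the whole cause. The rise of Rn18s-rs5, Rn7sk and Malat1 in P213L, which Bc1 did not share, cannot be told apart from the genotype for the microRNA rows. The slope on Rn18s-rs5, Rn7sk and Malat1 among libraries of the same group predicted a difference of 1.08 (95% interval -0.386 to 2.54). In the mean of the microRNA rows 0.57 was observed. Without WT replicate 3 the slope predicted -0.0326 (-0.635 to 0.569), against 0.25. The long RNAs of the cluster that holds Mir493 and Mir381 had log2 fold changes of 0.32 ± 0.33 (Meg3), 0.19 ± 0.17 (Mirg) and -0.02 ± 0.11 (Rian; SE), none past the threshold.

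In WT replicate 2 the choroid plexus list stood at a mean log2 value of 3.46 (0.73 to 0.99 in the other WT libraries) and Ttr at 10.25, mitochondrially encoded genes at 8.26 and Trib3 at 0.11. In WT replicate 1 the microglial genes Siglech (2.87) and Gpr34 (3.36) and 9630013A20Rik (2.03) were low.

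A count of 0 genes past the threshold in limma is reached by any split (35 of 35, highest other 0), which says nothing about chance. The 657 genes at an unadjusted p under 0.05 were reached by 7 of 35 splits with the genotype split counted (highest other 2527), so chance could not be excluded for that count. With sample weights limma called 3981 genes, and 4 of 35 splits gave as many (highest other 8458), so chance could not be excluded for them. A split that set WT replicates 2, 3 and 4 against the rest gave 2527 genes at an unadjusted p under 0.05. It differs from the genotype only in WT replicate 1, and the genotype comparison without that library gave 1574. The count thus cannot tell a structure other than genotype from WT replicate 1 differing within its group. The deviations from the gene means rose with GC content in WT replicate 1 (Spearman's rho 0.493 across genes), P213L replicate 1 (0.492) and P213L replicate 3 (0.298) and fell with it in the other 4 (-0.466 to -0.0838), a trend that crosses the groups, and genes are not independent replicates.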

How the results depend on the processing

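The protein-coding filter, the removal of the length and GC trend, leaving out WT replicates 2 and 3 together and leaving out WT replicate 3 with an estimated correlation were chosen after seeing the data. The count of 0 genes was unchanged in limma under every alternative except sample weights, which called 3981, with weights of 6.90 for P213L replicate 3 and 5.24 for WT replicate 4 against 0.0432 for WT replicate 3. Genes at an unadjusted p under 0.05 ran from 266 to 1574 when 1 library was left out, and were 1836 with no filter on low values, 361 at 5 TPM or more, 6969 with sample weights and 1118 with the trend removed. The myelinating list kept its direction in all alternatives, between -0.17 and -0.14 when 1 library was left out, and missed the threshold with an estimated correlation and in fry (-0.15 in both, adjusted p = 0.270 and 0.195), and with an estimated correlation without WT replicate 3 (-0.16, adjusted p = 0.418). The committed list passed with median-of-ratios scaling (-0.14), quantile normalization (-0.14), sample weights (-0.19), the trend removed (-0.19) and WT replicates 2 and 3 left out (-0.16), and ran from -0.16 to -0.014 when 1 library was left out, passing without WT replicate 3 or P213L replicate 1 (-0.06). Its main value was -0.06, and the cause was not tested. Of the 39 lists, 8 passed, 0 with an estimated correlation, with or without WT replicate 3, 0 in fry, 13 with the trend removed, 18 without WT replicates 2 and 3, and 7 to 17 when 1 library was left out, the highest without WT replicate 3. Signs reversed for the choroid plexus list without WT replicate 2 (0.10) and without WT replicates 2 and 3 (0.012), for the voltage-gated channel list without WT replicate 3 (-0.14) and without both (-0.11), for the postsynaptic list (-0.12 and -0.10) and the synaptic vesicle list (-0.11 and -0.10) likewise, for the ribosomal list without WT replicate 3 (0.021, with either correlation), for the erythroid list without both (0.20) and for the GABA receptor list without WT replicate 3 (-0.16) or P213L replicate 2 (-0.07), in each case with fewer samples. Signs also reversed with sample weights for the synaptic vesicle (-0.093) and GABA receptor (-0.17) lists, and with the trend removed for the synaptic vesicle (-0.11) and striatal (-0.096) lists. With 1 library left out the lists ran from -0.81 to 0.10 (choroid plexus), -0.14 to 0.28 (channels), -0.12 to 0.22 (postsynaptic), -0.11 to 0.11 (synaptic vesicle), -0.16 to 0.10 (GABA receptor) and -0.22 to 0.021 (ribosomal). A further 111 sign changes concerned 30 results past the threshold under neither setting. The replicate numbers did not pair all samples. The correlation of deviations was 0.128, 0.170 and -0.101 for numbers 1, 2 and 3, against at most 0.0407, 0.0432 and 0.121 with another number. A pairing for numbers 1 and 2 stays open. With the replicate number as a block 0 genes passed (500 at an unadjusted p under 0.05), the myelinating list stood at -0.14 and 6 lists passed. Sex as a covariate was not run because all 7 samples were male by expression. TPM keeps no counts, so counting error could not be separated from other spread.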

Other observations

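The tests of these lists were fixed before the data were examined, and leaving out WT replicate 3 was among the alternatives set then, while adding an estimated correlation to it was chosen after the result was seen. Genes of protein folding stress did not pass as a list (mean log2 fold change 0.13, camera adjusted p = 0.0959), though 5 of its 25 members were higher at an unadjusted p under 0.05. Trib3, a stress-induced pseudokinase, stood at 0.913 ± 0.223 TPM in WT and 1.74 ± 0.185 TPM in P213L, the chaperone Pdia4 at 53.0 ± 5.64 and 70.0 ± 3.04 TPM and the transcription factor Xbp1 at 74.6 ± 4.39 and 90.4 ± 0.859 TPM (SD, n = 4 and 3). Without WT replicate 3 the list passed (mean 0.16, adjusted p = 3.95e-04 in camera; adjusted p = 0.472 with an estimated correlation).

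Neuronal lists did not pass with all 7 libraries. Mean log2 fold changes were 0.16 for upper-layer and -0.04 for deep-layer excitatory neurons, 0.07 for all excitatory neurons and 0.10 for inhibitory neurons. Without WT replicate 3 the upper-layer list turned to -0.04 and that of all excitatory neurons to -0.02. Among inhibitory genes Vip, a peptide of an interneuron class, had a log2 fold change of -0.53 ± 0.19, and Dlx5 and Dlx2, transcription factors of young interneurons, of 0.38 ± 0.16 and 0.28 ± 0.12 (SE). Snap25, a protein of vesicle release, stood at 365.6 ± 33.0 TPM in WT and 292.8 ± 18.9 TPM in P213L. Trp73, a transcription factor of Cajal-Retzius neurons, rose adjusted over the list alone (log2 fold change 0.61 ± 0.18, SE), 1 of 5 members, and did not pass over all genes in limma. Without WT replicate 3 the astrocyte (-0.13), synaptic vesicle (-0.11), postsynaptic (-0.12), GABA receptor (-0.16) and voltage-gated channel (-0.14) lists passed on the lower side in camera at the preset correlation, and 0 of the 39 lists passed with an estimated correlation. With all 7 libraries their means were -0.05, 0.05, 0.12, 0.001 and 0.16, so 4 of these 5 signs turned with that library.

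Some rows of nuclear RNA or RNA without a poly(A) tail, chosen after their values were seen, separated the groups. The ribosomal RNA row Rn18s-rs5 stood at 17323 ± 4740 TPM in WT and 33789 ± 7829 TPM in P213L, the nuclear RNA Malat1 at 280.5 ± 133.1 and 528.8 ± 40.2 TPM, the small nuclear RNA Rn7sk at 8.37 ± 2.68 and 19.8 ± 6.29 TPM and the neuronal small RNA Bc1 at 289.4 ± 72.2 and 124.8 ± 57.4 TPM (SD, n = 4 and 3). The groups did not overlap for these 4 rows, and Bc1 moved the other way from the rest. Because the rows were chosen after their values were seen, this lack of overlap is no test of library composition. Among all tested genes 8.69% did not overlap. Cholesterol synthesis genes, which supply myelin membrane, had a mean log2 fold change of 0.10, with 19 of 24 members higher (camera adjusted p = 0.401). Mvd in it had 0.25 ± 0.13 (SE). The hnRNP family list had a mean of 0.03 and the splicing factor list of 0.05, with Tra2a, a splicing regulator, at 0.30 ± 0.10 (SE), and neither list passed (camera adjusted p = 0.547 and 0.483).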
